A study of Homo sapiens with 6 samples.

How the data were processed

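RNA from VCaP cells was measured on 6 Agilent human expression arrays with 2 colours. VCaP is an established prostate cancer cell line that carries the TMPRSS2-ERG fusion. Each array held RNA from cells given an siRNA in one dye and RNA from cells given a non-targeting control siRNA in the other. Per the labels, 4 arrays held DNA-PKcs siRNA (siRNA1 and siRNA2, each on 2 arrays with the dyes swapped) and 2 arrays held PARP1 siRNA, both with the siRNA RNA in Cy3. The sample titles number the PARP1 siRNAs as 1 and 2, while the names of the scanner files number both as siRNA2, so whether these 2 arrays carry 1 or 2 different siRNAs is open. Nothing in the labels says that the samples came from separate cultures, so p-values of single genes measure the spread between these arrays, which may be technical.

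Each scanner file held 45015 spots, of which 1639 were controls and 43376 were probe spots for 41000 distinct probes. Per the file headers, the arrays were of design 014850 and were quantified with Agilent Feature Extraction 9.5.1.1, with probe coordinates on hg18 (NCBI build 36). The deposited scanner files give mean spot intensity and local background intensity per channel, processed intensity after background subtraction and linear and lowess dye normalization, and a log10 ratio of Cy5 over Cy3. The deposited value table holds 1 column per sample on the log2 scale for 40968 probes, and every column has a median of 0.0. How the authors made that table is not given in the sources used here. For 5 of the 6 samples it equalled the scanner file's log ratio, converted to log2 and turned to siRNA over control: the correlation was at least 0.9998 and at least 99.492% of probes lay within 0.001. Its scale and direction were therefore known from these columns, and were taken to hold for the sixth. The tables left no per-sample column without a sample.

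For PARP1 siRNA replicate 1 the scanner file and the value table held different measurements: the correlation was -0.327, and 19.3% of probes lay within 0.001. In the value table PARP1 was low in this sample, as the label says, and in the scanner file it was not. The design fixed before the data were examined used normexp background correction and loess on the scanner files. Because of the mismatch, the log2 ratios of the authors' value table were used for all 6 samples instead, and the scanner-based version became an alternative. Background flags were taken from the 5 matching files only, so that PARP1 siRNA has 1 array with such flags.

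Spots of one probe were averaged, and control spots and spots marked as non-uniform or population outliers were left out of the scanner-based values. A probe was kept where it was well above background in at least 1 channel on at least 2 of the 5 arrays with a matching file, which left 26945 probes. Between 61.22% and 66.25% of the probes of each of these 5 arrays were well above background in at least 1 channel. The number of arrays limits the precision. Probes were named through their accession (23958 probes), through a current symbol (2755) or through an older symbol (1032) in a RefSeq gene table, and 13255 kept the name in the file. For a gene with several kept probes the brightest stood for the gene, which gave 19759 genes, 13286 of them with a reference symbol.

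limma 3.58.1 with statmod 1.5.0 in R 4.3.3 was used on the log2 ratios, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Each control RNA serves as 1 control sample inside the ratio, so the test of a ratio against 0 leaves out the control's own spread. For DNA-PKcs siRNA the 2 arrays of each dye swap were averaged, and these 2 values were fitted together with the 2 PARP1 siRNA arrays, which share the estimate of the spread (2 residual and 2.39 prior degrees of freedom). For PARP1 siRNA, and for PARP1 siRNA minus DNA-PKcs siRNA, all 6 arrays were fitted with a dye term, since both PARP1 arrays had the same orientation, and with siRNA as a random block (correlation 0.0859, 3 residual and 2.75 prior degrees of freedom). Values of PARP1 siRNA are given after the dye term was taken off unless stated. An SD is that over the 2 siRNAs (DNA-PKcs) or over the 2 arrays (PARP1), with n = 2. Arrays 1 and 2 of DNA-PKcs siRNA shared a slide, as did arrays 3 and 4, so slide and dye orientation coincide there. By the file headers no slide held more than 1 group, and a slide block between groups was therefore not fitted. The slide of PARP1 siRNA replicate 1 was read from its mismatched file, so the sample's own slide is not known.

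The genes named in the text followed a rule set in advance: PRKDC, PARP1, ERG, KLK3, TMPRSS2, EZH2 and PLA1A always, the 12 largest log2 ratios in each direction among genes with a symbol past the threshold that moved the same way in both siRNAs or arrays, and up to 4 members of each gene list with the smallest p. For the difference between knockdowns the rule took the 5 smallest p in each direction, since no gene passed. One gene of the rule, which is Y-linked, and some others of the rule are not reported here. Genes named outside the rule are said to be so. A gene that was not well above background on any array of one side is given as "at least N-fold", from normalized channel levels of the matching files after loess and quantile scaling of mean intensity, against the higher of the array's lowest signal well above background and the probe's own signal. For PARP1 siRNA such a level comes from 1 array without a dye swap and is open to dye bias.

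In all, 28 gene lists were fixed in advance and tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera compares a list's genes with all other genes. Its p at the preset correlation rests on the spread across genes, counted as nearly independent, and not on the spread between arrays. They covered G1/S and G2/M genes, 4 DNA repair and damage groups, ADP-ribosylation enzymes, ERG-activated genes, the ETS family, androgen-regulated genes, p53 targets, apoptosis, interferon and NF-kB genes, cholesterol synthesis, oxidative phosphorylation, hypoxia, chaperones, the unfolded protein response, ribosomal proteins, histones, Wnt, epithelial and mesenchymal genes, and markers of neuroendocrine, fibroblast, leukocyte and endothelial cells. Camera with an estimated correlation, and fry's directional test, were the alternatives. With an estimated correlation, camera has only the fit's 2 or 3 residual degrees of freedom. Over 28 lists it then has little power, so a lost call does not show that correlated genes made it. The fibroblast markers with DNA-PKcs siRNA lost theirs at an estimated correlation of -0.109. For the other lists called with DNA-PKcs siRNA the estimates ran from 0.0247 (base excision and single-strand break repair) to 0.847 (G1/S and replication). These lie above the preset of 0.01, so correlated genes may have contributed to those calls. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

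The fits were tested on simulated data with the real genes' spread. With no change simulated, 0 genes were called in each of the 3 comparisons. The simulated ratios held no deviation of a control shared by all arrays, so calls that such a deviation gives could not appear. Among 19759 genes of which only 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold, the DNA-PKcs fit recovered 0%, 28.4% and 93.9% of them, the PARP1 fit 0%, 9% and 89.4%, and the difference 0%, 0% and 84.8%. With many other genes changed as well, as in the data for each knockdown against control, the recovery was 59.7%, 92.5% and 100% for DNA-PKcs. It was 34.3%, 89.6% and 98.5% for PARP1, and 23.9%, 77.6% and 97% for the difference. For the difference 0 genes passed in the data, so the setting with few changed genes is the nearer one there. A simulated shift of 1 list was found by camera in both comparisons, and 0 of the other 27 lists were called. Unchanged samples against a single control, given the same spread as the siRNA values, were simulated 100 times. They give the correlation across genes that such a control alone produces. For shared genes no test was run on them. As many top and bottom genes, ranked by ratio over spread, were taken as were called in the data.

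The alternatives tried were no background correction, normexp with an offset of 0, median centring in place of loess, Agilent's own log ratio, the scanner files as first designed, no filter and a stricter filter on dim probes, the mean of a gene's probes, a variance trend with and without robust estimation, other designs (6 arrays, 4 DNA-PKcs arrays alone, no dye term, no block, siRNA number as a replicate block) and leaving out each array or siRNA. Scanner-based alternatives used the value table for PARP1 siRNA replicate 1, except in the version as first designed. Leaving out 1 array left too few arrays to estimate the block correlation, and that of all 6 arrays was kept. Where 1 PARP1 siRNA array was left, it was assumed to vary like the DNA-PKcs siRNA arrays. Chosen after seeing the data were normexp and loess on the 5 matching files and the DNA-PKcs fit without PARP1 siRNA replicate 1.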

Results

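The arrays measured mRNA in VCaP prostate cancer cells after siRNA against DNA-PKcs or against PARP1. DNA-PKcs is the catalytic subunit of the kinase that acts in the joining of broken DNA ends. PARP1 attaches poly(ADP-ribose) to proteins at DNA breaks. Each siRNA sample was hybridised against RNA of cells given a control siRNA. There were 4 arrays for DNA-PKcs siRNA, as dye swaps of 2 siRNAs, and 2 arrays for PARP1 siRNA. Per the series title, the study concerned PARP inhibition where a prostate cancer carries an ETS fusion, and the arrays ask how the cells' expression differs once either enzyme is depleted. Values are log2 ratios of siRNA over control siRNA, with the SD over the 2 siRNAs of DNA-PKcs or the 2 arrays of PARP1 siRNA. In all, 19759 genes were tested.

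The targeted mRNAs were low in the samples named for them. PRKDC, the gene of DNA-PKcs, had log2 ratios of -1.22, -1.20, -1.05 and -0.92 on the 4 DNA-PKcs siRNA arrays and of -0.06 and -0.07 on the PARP1 siRNA arrays (probe on chromosome 8, 48848854 to 48848913, hg18). PARP1 had log2 ratios of -1.61 and -0.72 on the PARP1 siRNA arrays and of 0.05, -0.09, -0.03 and 0.09 on the DNA-PKcs siRNA arrays (probe on chromosome 1, 224615440 to 224615498). PRKDC fell 2.14-fold with DNA-PKcs siRNA, to a mean log2 ratio of -1.10 ± 0.06 (SD, n = 2; limma, adjusted p = 0.0141). PARP1 fell 2.28-fold with PARP1 siRNA, to -1.19 ± 0.62 (n = 2; adjusted p = 0.0418). A second, dimmer PRKDC probe (chromosome 8, 48956534 to 48956593) read -0.76, -0.51, -0.65 and -0.39 with DNA-PKcs siRNA but 0.97 and 0.63 with PARP1 siRNA, so the probes of PRKDC disagree in the PARP1 samples. The scanner file deposited for the first PARP1 siRNA sample holds another measurement than the value table, and the values here are those of the table.

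**Figure D1:**
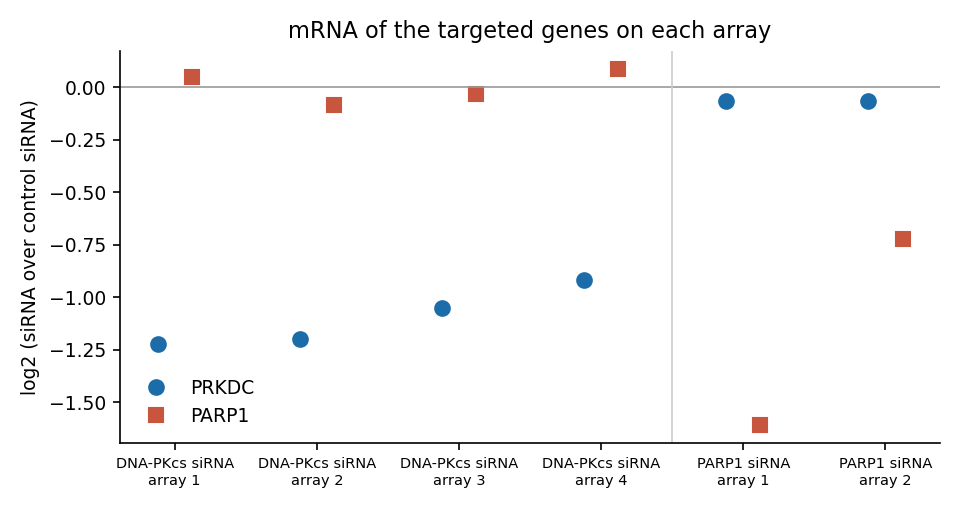
Log2 ratio of siRNA over control siRNA (vertical axis) of PRKDC (circles) and PARP1 (squares) on each of the 6 arrays (horizontal axis), before any dye correction. PRKDC lies between -1.22 and -0.92 on the DNA-PKcs siRNA arrays, and PARP1 at -1.61 and -0.72 on the PARP1 siRNA arrays.

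DNA-PKcs siRNA was accompanied by lower mRNA of the DNA replication machinery and of the enzymes that make cholesterol. Of 40 measured G1/S and replication genes, 29 fell and 0 rose, with a median log2 ratio of -0.831. Of 29 measured genes of cholesterol synthesis, 15 fell and 0 rose, with a median of -0.455. Neither list passed with an estimated correlation (adjusted p = 0.866 with an estimated correlation for each). That test has few degrees of freedom, so a loss there does not tell correlated genes from low power. Members of DNA repair lists fell more often than they rose. ERG, the oncogenic transcription factor of the TMPRSS2-ERG fusion, rose 2.13-fold, and TMPRSS2, the androgen-driven partner of that fusion, fell 1.91-fold. Over all genes, 7043 of 19759 (35.6%) passed an adjusted p of 0.05, 3390 of them higher and 3653 lower, and 1786 differed at least 2-fold.

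Among the G1/S and replication genes, RRM2, a subunit of the ribonucleotide reductase that supplies deoxynucleotides, fell to -1.32 ± 0.12 (adjusted p = 0.0142). Both of its probes were lower. RFC2, of the clamp loader, fell to -1.24 ± 0.09 (adjusted p = 0.0149), and the replicative helicase subunits MCM2 and MCM7 fell to -1.13 ± 0.13 and -1.11 ± 0.21. The list passed camera at an adjusted p of 4.44e-07 (adjusted p = 0.866 with an estimated correlation), and 30 of its members were lower when adjusted over the list alone. Of 45 G2/M and mitosis genes, 17 fell and 2 rose, with a median of -0.254 (adjusted over the list alone, 17 lower and 3 higher; camera adjusted p = 0.00376, and adjusted p = 0.866 with an estimated correlation). The mitotic kinases AURKB and CDK1 fell to -1.09 ± 0.10 and -0.98 ± 0.09, and the topoisomerase TOP2A to -0.83 ± 0.12. CENPF fell to -0.64 ± 0.03 on its brighter probe while its other probe was higher, at 1.03.

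In the repair lists, 12 of 42 genes of homologous recombination fell and 2 rose (adjusted over the list alone, 16 and 2; median -0.32; camera adjusted p = 0.00143, and adjusted p = 0.866 with an estimated correlation). The nuclease subunit EME1 fell to -0.98 ± 0.02, the Holliday junction resolvase GEN1 to -1.41 ± 0.57 and the Fanconi anaemia gene FANCE to -0.71 ± 0.02. FANCC rose to 0.75 ± 0.03 on its brightest probe, with its other probes near 0. Of 30 genes of base excision and single-strand break repair, 14 fell and 2 rose (adjusted over the list alone, 16 and 2; median -0.37; camera adjusted p = 0.00314, and adjusted p = 0.866 with an estimated correlation). PCNA, the sliding clamp of replication and repair, fell to -0.99 ± 0.02. LIG3 and HMGB1 had probes past the threshold in opposite directions, at -0.76 and 1.83 for LIG3 and at 0.86 and -0.54 for HMGB1. In DNA damage signalling, 10 of 24 genes fell and 1 rose (adjusted over the list alone, 11 and 2; median -0.52; camera adjusted p = 0.0142, and adjusted p = 0.976 with an estimated correlation). The checkpoint kinase CHEK1 fell to -0.99 ± 0.04 and the deubiquitinase USP1 to -1.02 ± 0.20. In non-homologous end joining, the pathway of DNA-PKcs, 7 of 21 genes fell and 0 rose (adjusted over the list alone, 7; median -0.203; camera adjusted p = 0.0491, and adjusted p = 0.866 with an estimated correlation). That call was lost with the mean of a gene's probes (camera adjusted p = 0.0647) and with the spread taken from the DNA-PKcs siRNA values alone (0.057). Besides PRKDC, a member of that list, the 7 included RIF1, 2.0-fold lower on its brightest probe, with 2 others at -1.27 and -1.58 also past the threshold and 1 near 0, and the end-joining ligase LIG4, at -0.72 ± 0.23, which was well above background in the siRNA channel on 1 of 4 arrays.

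The cholesterol synthesis list passed camera at an adjusted p of 5.31e-05 (adjusted p = 0.866 with an estimated correlation; 16 lower adjusted over the list alone). HMGCS1, which makes HMG-CoA, fell to -1.35 ± 0.08 on its brighter probe and was also lower on the other. The mevalonate pathway enzymes MVD and IDI1 fell to -1.18 ± 0.18 and -1.02 ± 0.01, and the fatty acid desaturase SCD to -1.37 ± 0.21 on its brightest probe, with its other probes not past the threshold. Of 44 genes of oxidative phosphorylation, 15 fell and 5 rose (adjusted over the list alone, 18 and 8; median -0.221; camera adjusted p = 0.0491, and adjusted p = 0.976 with an estimated correlation). With the mean of a gene's probes that call was lost too (camera adjusted p = 0.0661). The succinate dehydrogenase subunits SDHA and SDHC fell to -1.02 ± 0.04 and -0.96 ± 0.11, and CYC1 to -1.06 ± 0.05. CYCS fell to -1.67 ± 0.34 on its brightest probe while another of its probes was higher, at 0.55. Among 19 heat shock and chaperone genes, 9 fell and 2 rose (the same counts adjusted over the list alone). The list did not pass (camera adjusted p = 0.0569, and adjusted p = 0.866 with an estimated correlation). It passed with the mean of a gene's probes (camera adjusted p = 0.0311) and with median centring (0.0404). The HSP90 co-chaperones AHSA1 and STIP1 lay at -0.89 ± 0.03 and -0.83 ± 0.01, and HSP90AB1 at -0.92 on its brightest probe but 0.83 on another.

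Of 9 measured markers of fibroblasts, 4 rose and 0 fell with DNA-PKcs siRNA (the same counts adjusted over the list alone; median 0.538; camera adjusted p = 0.0491, and adjusted p = 0.866 with an estimated correlation). The call was lost with the mean of a gene's probes (camera adjusted p = 0.104). The 4 were the matrix genes COL6A1, at 0.89 ± 0.10, COL1A1, at 0.57 ± 0.08, DCN, whose control was not well above background (at least 1.04-fold higher), and FBLN1, at 1.27 ± 0.06 on its brighter probe and -0.87 on the other. Of 15 NF-kB and inflammatory genes, 6 rose and 0 fell, adjusted over the list alone as well, and the list did not pass (median 0.3; camera adjusted p = 0.0817). Its members LTB, ICAM1, RELB and CCL2 rose to 1.61 ± 0.11, 1.08 ± 0.09, 1.11 ± 0.05 and 1.07 ± 0.39.

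Of the prostate genes named in advance, ERG rose to 1.09 ± 0.10 (adjusted p = 0.0196; probe on chromosome 21, 38676351 to 38676410). Its other probes read 0.98 and 0.07. TMPRSS2 fell to -0.94 ± 0.03 (adjusted p = 0.0147; chromosome 21, 41758774 to 41758833), the histone methyltransferase EZH2 fell to -1.22 ± 0.02 (adjusted p = 0.0236), and the phospholipase PLA1A rose to 0.72 ± 0.00 (adjusted p = 0.0215). KLK3, which encodes PSA, had a log2 ratio of 0.46 ± 0.04 that did not pass (adjusted p = 0.0622), with other probes at -1.54 and -0.67. Of 38 androgen-regulated genes 7 fell and 1 rose (adjusted over the list alone, 4 and 0; median -0.252; camera adjusted p = 0.0597), including the transcription factor MAF, 2.0-fold lower with both probes lower, ORM1, at -1.23 ± 0.29, and ADAM7, at -0.88 ± 0.27. Of 24 ERG-activated genes 6 rose and 1 fell (adjusted over the list alone, 5 and 1; median 0.183; camera adjusted p = 0.169). ARHGDIB and NKAIN1 rose to 1.17 ± 0.02 and 1.16 ± 0.17, and the matrix protease MMP9 to 0.81 ± 0.08. Of 17 genes of the ETS family 5 rose and 0 fell, adjusted over the list alone as well (median 0.00737; camera adjusted p = 0.372), with EHF at 1.42 ± 0.07 and ETV6 at 0.83 ± 0.17.

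Among the largest rises with DNA-PKcs siRNA were those of PTPRT, whose control was not well above background (at least 2.07-fold higher), the phosphatase PTPRE (3.18 ± 0.39), the chromatin organiser SATB1 (2.97 ± 0.22), MRAS (2.83 ± 0.01), SLFN5 (2.73 ± 0.20), IFI27L2 (2.67 ± 0.02), the trefoil factor TFF3 (2.67 ± 0.00, with its 3 probes all higher), WNK4 (2.63 ± 0.07), FOXN2 (2.59 ± 0.25), IGFBP7 (2.56 ± 0.18) and the U12 small nuclear RNA RNU12 (2.53 ± 0.13). The control signal of PTPRE and of WNK4 was well above background on 1 of 4 arrays. The largest falls with a level on both sides were those of PLAUR, the urokinase receptor (-2.15 ± 0.03), TGFB2 (-2.13 ± 0.41), FAM13A-AS1 (-2.01 ± 0.41) and SLC6A13 (-1.96 ± 1.08), each well above background in the siRNA channel on 1 or 2 of 4 arrays. The kinase MAK (at least 1.42-fold lower), ST20-AS1 (1.37), OR2B6 (1.27), IGHA1 (1.2), MARS2 (1.15), UCA1 (1.12) and SLC15A2 (1.06) were not well above background on any siRNA array.

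Limma called 0 genes without siRNA1 or without siRNA2 (4457 and 3946 at an unadjusted p below 0.05), where 1 DNA-PKcs siRNA value is left, the spread comes from the PARP1 siRNA arrays and all 85 named genes kept their direction, and 0 with median centring in place of loess (4845 unadjusted). Median centring shifted the median of all genes by -0.365 for DNA-PKcs siRNA and by -0.104 for PARP1 siRNA, and turned the signs of PLA1A, LIG4, FANCC, ISG20 and BAX with DNA-PKcs siRNA and of HRK with PARP1 siRNA. Without the first PARP1 siRNA array the spread comes from the DNA-PKcs siRNA values alone, as it would without the second, and 11051 genes passed. The log2 ratios of 2 probes of a gene correlated at 0.865 across 661 pairs up to 200 bases apart and at 0.237 across 5549 pairs over 2000 bases apart. Of the genes with several probes, 326 of 5364 had probes past the threshold in both directions.

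**Figure D2:**
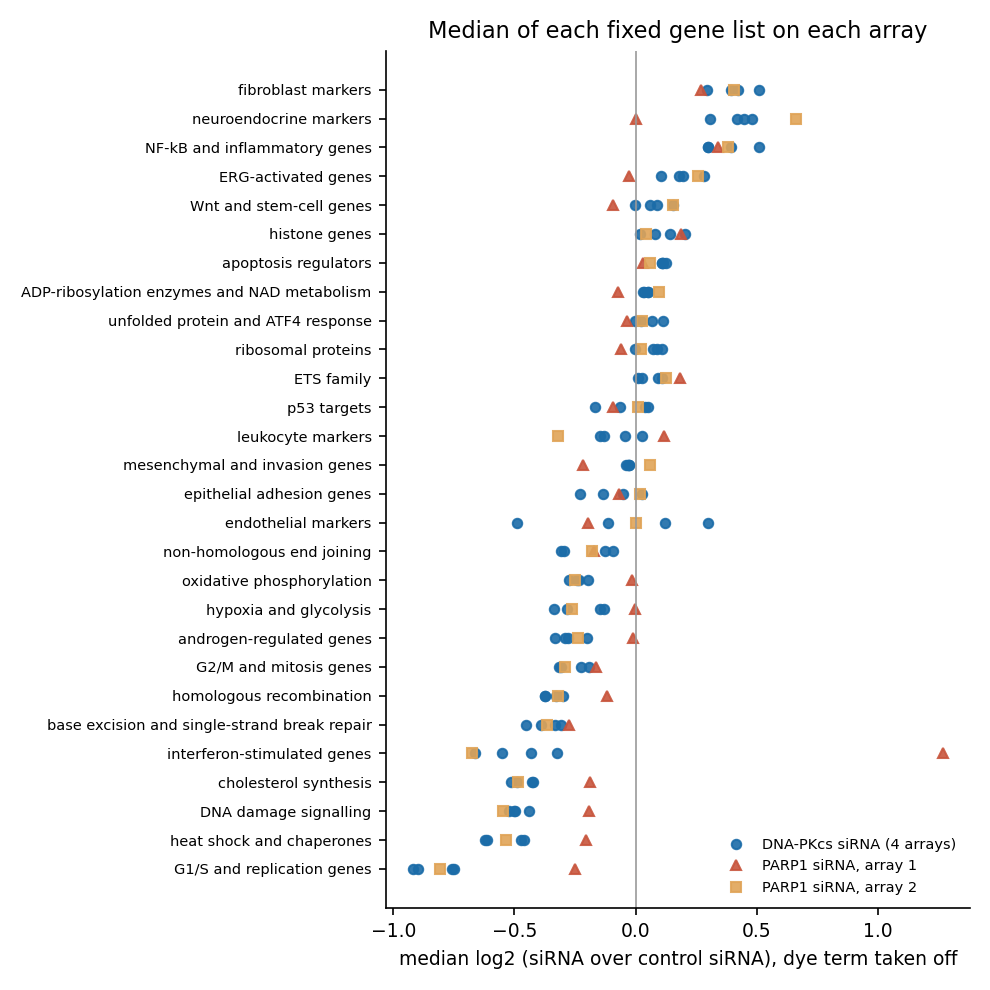
Median log2 ratio of siRNA over control siRNA, with the dye term taken off (horizontal axis), of the measured genes of each of the 28 fixed lists (vertical axis) on the 4 DNA-PKcs siRNA arrays (circles) and PARP1 siRNA arrays 1 (triangles) and 2 (squares). The interferon-stimulated genes lie at 1.27 on PARP1 siRNA array 1 and at -0.676 on array 2, and the G1/S and replication genes at -0.249 and -0.809.

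With PARP1 siRNA, the lists of G1/S and replication, G2/M and mitosis, cholesterol synthesis, base excision repair and homologous recombination genes were lower by camera. Each of these 5 calls was lost with an estimated correlation, a test with little power here (adjusted p = 0.834 with an estimated correlation for each). Their estimated correlations ran from 0.0584 for base excision repair to 0.708 for the G1/S and replication genes. ERG rose 1.93-fold and TMPRSS2 fell 1.68-fold. RNA of MALAT1, a nuclear long noncoding RNA, and of the RNA helicase DDX17 rose over 4-fold on the probes used. The other probes of MALAT1 did not pass, and a further probe of DDX17 lay near 0. Over all genes, 2282 of 19759 (11.5%) passed, 1338 of them higher and 944 lower, and 885 differed at least 2-fold. The 2 arrays correlated at 0.585 across genes, a value that their shared control raises.

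Of the 40 G1/S and replication genes, 3 fell and 0 rose with PARP1 siRNA, and 17 were lower when adjusted over the list alone (median -0.529; camera adjusted p = 1.07e-05, and adjusted p = 0.834 with an estimated correlation). RRM2 fell to -1.08 ± 0.22, the cyclin CCNE2 to -1.29 ± 0.65 and MCM2 to -0.92 ± 0.40. The median of this list was -0.809 without the first PARP1 siRNA array, where 21 members fell, and -0.249 without the second, where 0 did. Of 45 G2/M and mitosis genes 9 fell and 0 rose, adjusted over the list alone as well (median -0.219; camera adjusted p = 0.0028, and adjusted p = 0.834 with an estimated correlation), including AURKB, at -0.96 ± 0.24, the proliferation marker MKI67, at -0.85 ± 0.27, CDC20, at -0.73 ± 0.12, and NUF2, at -0.61 ± 0.00. Without the first array 4 of them fell (median -0.292), and without the second 0 (median -0.163).

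Of 29 genes of cholesterol synthesis, 5 fell and 0 rose (adjusted over the list alone, 7; median -0.318; camera adjusted p = 0.000635, and adjusted p = 0.834 with an estimated correlation), with HMGCS1 at -1.30 ± 0.11 and MVD at -1.43 ± 0.21. The cholesterol synthesis median was -0.485 without the first array and -0.19 without the second. In base excision and single-strand break repair, the pathway PARP1 serves and a list that holds PARP1 itself, 3 of 30 genes fell and 0 rose (adjusted over the list alone, 7 lower and 1 higher; median -0.3, and -0.364 and -0.275 without the first and the second array; camera adjusted p = 0.00102, and adjusted p = 0.834 with an estimated correlation). Besides PARP1 they included LIG3, at -0.93 ± 0.03 on the brighter probe and 1.61 on the other. In homologous recombination 4 of 42 genes fell and 1 rose, adjusted over the list alone as well (median -0.231, and -0.32 and -0.118 without the first and the second array; camera adjusted p = 0.0116, and adjusted p = 0.834 with an estimated correlation). Without the second array the call was lost (camera adjusted p = 0.295). EME1 lay at -1.11 ± 0.02 and FANCE at -0.71 ± 0.04.

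With PARP1 siRNA, ERG rose to 0.95 ± 0.41 (adjusted p = 0.0383; other probes 0.94 and 0.13) and TMPRSS2 fell to -0.75 ± 0.09 (adjusted p = 0.0259). The values of EZH2 (-0.99 ± 0.59, adjusted p = 0.0614), PLA1A (0.54 ± 0.24, adjusted p = 0.0698), KLK3 (0.77 ± 0.30, adjusted p = 0.0677; other probes -0.62 and -0.10) and PRKDC (-0.18 ± 0.00, adjusted p = 0.331) did not pass. The dimmer PRKDC probe was higher, at 0.74, and passed when all kept probes were tested (limma, adjusted p = 0.0451). Of 38 androgen-regulated genes 3 fell and 0 rose, adjusted over the list alone as well (median -0.125; camera adjusted p = 0.297), with MAF at -0.94 ± 0.09 and the methyltransferase GNMT at -0.81 ± 0.28. Among the ETS family 2 of 17 rose (adjusted over the list alone, 3; median 0.155; camera adjusted p = 0.362), with EHF at 1.29 ± 0.24. Of 24 ERG-activated genes 0 passed in limma (median 0.115, camera adjusted p = 0.267). Their median was -0.0292 on the first array and 0.258 on the second.

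The largest rises with PARP1 siRNA that were measured above background were PTPRE (2.57 ± 0.95 on its brighter probe, with the other at 0.39), SLFN5 (2.42 ± 0.61), FOXN2 (2.28 ± 0.02) and HECTD4 (2.25 ± 0.13). MALAT1 (2.17 ± 0.63 on its brightest probe, with others at 0.50, 0.41 and -0.61), RNU12 (2.12 ± 0.31), DDX17 (2.12 ± 0.02, with a further probe at 1.47, also past the threshold, and another at -0.05) and RASSF4 (2.09 ± 0.29 on its brighter probe, with the other at -0.39) followed. FAM135B was at least 1.32-fold higher against a control not well above background, and SOX30, TOX and ARHGEF38 passed while neither channel was well above background. All of the 12 largest falls lay in genes that were not well above background in the siRNA channel of the array with such flags: MAK (at least 1.6-fold lower), FAAP24 (1.33), IGHA1 (1.3), ABHD17B (1.26), IGFBP1 (1.23), CAMKMT (1.2), HYCC1 (1.15), KCNH4 (1.13), NOTCH1 (1.12), SDR9C7 (1.06), CNDP1 (1.04) and GLRB (1.03).

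Limma called 2826 genes without the first PARP1 siRNA array, 0 without the second (4912 at an unadjusted p below 0.05), and 0, 0, 0 and 521 without DNA-PKcs siRNA arrays 1 to 4 (5611, 5589, 4737 and 5335 unadjusted). It called 0 with median centring (1440 unadjusted), and 4758 in a fit of 4 values (averaged dye swaps) that also has no dye term, of which 48.6% were higher against 58.6%. Probe pairs of one gene correlated at 0.786 up to 200 bases apart and at 0.175 over 2000 bases apart, and 48 of 5364 genes had probes past the threshold in both directions.

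Genes moved in step under both knockdowns. Of the 1338 genes that rose with PARP1 siRNA, 1228 (91.8%) also rose with DNA-PKcs siRNA, and of the 944 that fell, 846 (89.6%) also fell, where independent lists would share 230 and 175. Both comparisons share a control, and simulated unchanged samples against a single control, added after the overlap was seen, shared 889 and 691 on average and 929 and 723 at most in 100 simulations. The simulated lists were the top and bottom genes, set to the sizes of the called lists, and were not themselves called by a test. PTPRE (on its brighter probe), SLFN5, FOXN2 and RNU12 were among the largest rises of both, MAK and IGHA1 among the largest falls, and 4 genes passed in opposite directions. The log2 ratios of both comparisons correlated at 0.829 across genes, where unchanged samples against a single shared control gave 0.667 on average and 0.687 at most in 100 simulations. Their covariance was 0.278, against 0.0633 in the simulations, a difference of 0.214. The first PARP1 siRNA array correlated with the DNA-PKcs mean at 0.595 and the second at 0.855. The simulations give the control the same spread as an siRNA value, and the arrays give no second control to split. Part or all of the excess may therefore come from the shared control.

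**Figure D3:**
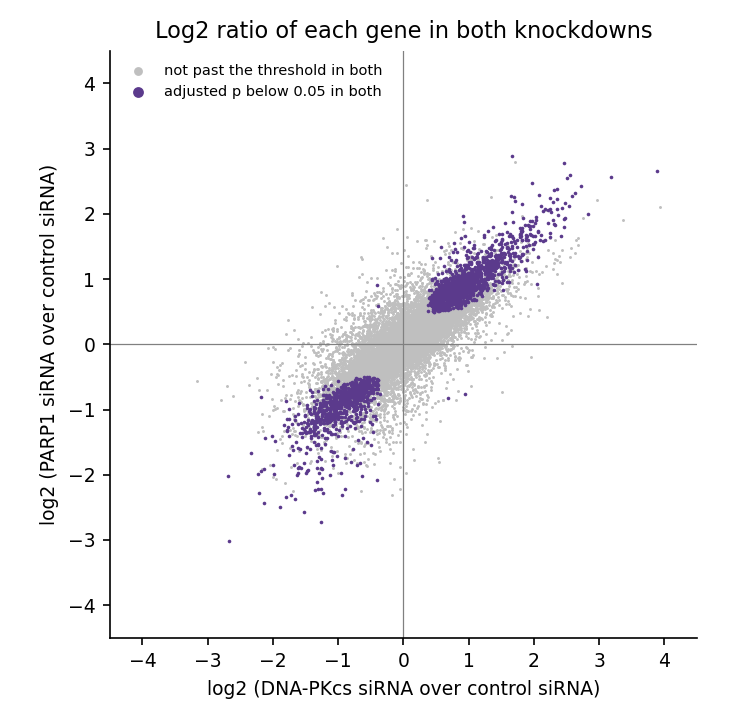
Log2 ratio of each of the 19759 genes with DNA-PKcs siRNA (horizontal axis) and with PARP1 siRNA (vertical axis), each over control siRNA; dark points passed an adjusted p of 0.05 in both. The points lie along the diagonal (r = 0.829), with 1228 genes higher in both and 846 lower in both.

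Tested directly, no single gene passed for the difference between the knockdowns. With few genes changed in the simulations, this test recovered 0% of 2-fold changes, so it could miss real ones. For PARP1 siRNA minus DNA-PKcs siRNA limma called 0 of 19759 genes (928 at an unadjusted p below 0.05, where chance gives 988), and the targets themselves did not pass: the difference was 0.92 for PRKDC (adjusted p = 0.546) and -1.19 for PARP1 (adjusted p = 0.776). The smallest p values above 0 belonged to CIB3, ZNF43, ARHGEF38, KRT84 and PRKDC, and below 0 to KCNH4, ZNF396, TPD52L3, SYDE1 and ANGPTL6, with adjusted p values from 0.427 to 0.546. Apart from PRKDC none of these was well above background in both channels of all arrays with such flags, so no size is given. As lists, 4 of the 28 differed by camera: interferon-stimulated genes (median difference 0.648, adjusted p = 2.19e-05), G1/S and replication genes (0.274, adjusted p = 2.19e-05), oxidative phosphorylation (0.103, adjusted p = 0.0108) and cholesterol synthesis (0.168, adjusted p = 0.0316). None of these 4 held with an estimated correlation, a test with little power here (adjusted p = 0.858 for each). Their estimated correlations ran from 0.277 for cholesterol synthesis to 0.76 for the interferon-stimulated genes. The other 24 lists did not pass, the closest being homologous recombination, androgen-regulated genes and endothelial markers (adjusted p = 0.114 for each).

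The differences of these lists followed the first PARP1 siRNA array. The interferon-stimulated genes, the antiviral genes that type I interferon induces, had a median of 1.27 on that array, with 41 of 43 above 0, and of -0.676 on the second, with 10 of 43 above 0, against -0.432, -0.552, -0.324 and -0.664 on the DNA-PKcs siRNA arrays. Without the first array the median difference of the interferon-stimulated genes turned to -0.172, still called by camera but with the opposite sign. It sets the second PARP1 siRNA array alone, at -0.676, against DNA-PKcs siRNA arrays that reach -0.664, so an opposite difference is not established. The other 3 lists were not called. That of the G1/S and replication genes turned to -0.00628, that of cholesterol synthesis turned to -0.00925 and that of oxidative phosphorylation shrank to 0.000692. The spread was taken from the DNA-PKcs siRNA arrays, since 1 PARP1 siRNA array was left. Examples chosen after their values were seen are IFI44L, at 2.61 and -3.74 on the PARP1 siRNA arrays and -3.17 with DNA-PKcs siRNA, IFIT1, at 2.99, -2.54 and -1.67, MX1, at 2.49, -2.27 and -1.41, and OAS1, at 1.73, -1.85 and -2.08. With DNA-PKcs siRNA 3 of the 43 interferon-stimulated genes fell and 2 rose (adjusted over the list alone, 0 and 1; median -0.453; camera adjusted p = 0.31), and 22 fell and 6 rose with the spread taken from the DNA-PKcs siRNA values alone (camera adjusted p = 0.00473, and adjusted p = 0.807 with an estimated correlation). IRF1 fell to -0.65 ± 0.10, the 3'-5' exonuclease ISG20 rose to 0.67 ± 0.16, and the kinase EIF2AK2 rose to 1.65 ± 0.14 on its brighter probe, with the other at -0.42. With PARP1 siRNA 2 of the 43 rose and 0 fell (adjusted over the list alone, 1 and 0; median 0.158; camera adjusted p = 0.297), EIF2AK2 at 1.66 ± 0.18 and PARP14 at 1.58 ± 0.95. The list's median with PARP1 siRNA was -0.676 without the first array and 1.27 without the second, each resting on the 1 array left.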

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

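Of the tests in this part, those of the scanner file and of the control-free contrast were chosen after the results were seen, while those of probe distance, of the shared control and of leaving out the first PARP1 siRNA array were written before. The gap test for a sample far from the others was run on 92 named genes over the 4 DNA-PKcs siRNA arrays and picked out 0. Its values had the dye term taken off, which is estimated from these same arrays. Both dye orientations then have the same mean, and the gap stays too small for the test to pick out any array. The 0 therefore does not show whether an array lies far from the others.

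A signal stood in data that no comparison uses: PRKDC had a log2 Cy5 over Cy3 of -1.22 in the scanner file deposited for the first PARP1 siRNA sample, whose own value table gives -0.06. If that file held the same array with the dyes turned, PARP1 would lie near 1.61 in size. It lay at -0.0643, which argues against that. A DNA-PKcs siRNA array with the siRNA RNA in Cy5 would show PRKDC near the -1.21 of those arrays, and the file's -1.22 and its correlations of 0.759 and 0.824 with them, against 0.771 between them, are what such an array would give. No biological explanation was tested, since the design gives none for a file.

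The log2 ratios of both knockdowns moved together across genes. Chance deviation of the shared control gave covariances up to 0.0686 in simulations, below the observed 0.278, but the simulations take the control's spread from the siRNA arrays and there was 1 kind of control RNA, so a larger deviation of the control and a shared response to both knockdowns cannot be told apart. RNA quality or priming that differed between control and siRNA RNA may also contribute. The correlation of probe pairs fell by 0.628 with distance with DNA-PKcs siRNA. Where the control cancels, it fell by 0.421 in the first PARP1 siRNA array minus DNA-PKcs siRNA, and by 0.335 with both PARP1 siRNA arrays. This explanation therefore cannot be told apart from transcript differences.

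Between the knockdowns, 4 lists differed by camera: interferon-stimulated genes (median difference 0.648), G1/S and replication genes (0.274), cholesterol synthesis (0.168) and oxidative phosphorylation (0.103), each lost with an estimated correlation (adjusted p = 0.858 with an estimated correlation). Were the first PARP1 siRNA array alone the source, the differences would shrink or turn without it. That of the interferon-stimulated genes turned to -0.172 and that of the G1/S and replication genes to -0.00628, so the positive differences rest on that array. Camera still called the interferon-stimulated genes, with the opposite sign. The remaining -0.172 sets the second PARP1 siRNA array alone, at a median of -0.676, against DNA-PKcs siRNA arrays that reach -0.664. An opposite difference is therefore not established. Whether the first PARP1 siRNA array differs through its siRNA, its culture or its handling was not tested. No biological explanation was tested, since no other array carries that sample.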

How the results depend on the processing

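Signal over background limits the dim genes: with 1 knockdown, those below background in a channel on all its arrays are given as lower bounds, for PARP1 siRNA from 1 array. Of the genes named for the difference, PRKDC and PARP1 alone were above background in both channels on all arrays with flags. Of 85 named genes past the threshold with DNA-PKcs siRNA, 78 kept their direction in all 22 alternatives and 0 kept their call in all; with PARP1 siRNA 39 of 55 kept their direction in all 19, and 0 their call. A fit with the slide as a block was not run. The samples share only a number: with the siRNA number as a replicate block the difference between the knockdowns had 0 genes (1565 at an unadjusted p below 0.05).

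For the genes past the threshold, median centring in place of loess gave 0 with DNA-PKcs siRNA (4845 unadjusted) and 0 with PARP1 siRNA (1440), and the scanner files as first designed gave 0 (28) and 0 (6); in the latter, the mismatched file is part of the fit. Without a filter there were 1697 and 730 of 30455 genes. With DNA-PKcs siRNA the 6-array fit gave 11053, the 4 DNA-PKcs arrays alone 11990, and the averaged fit without the first PARP1 siRNA array, chosen after seeing the data, 11051. Leave-outs ranged from 0 to 11608. With PARP1 siRNA no background correction gave 3784, the 5 matching files (chosen after seeing the data) 3606, both channels above background 3891, a variance trend 4370, a trend with robust estimation 4498 and the fit of 4 values without a dye term 4758. Leave-outs ranged from 0 to 2826. For the difference there was 1 gene without the first PARP1 siRNA array (956 unadjusted) and 0 otherwise. Camera with an estimated correlation and fry's directional test called 0 lists in each comparison. Of the 5 lists with PARP1 siRNA, no background correction, the 5 matching files, no filter and both channels above background each gave 8, the files as first designed 1, and leave-outs up to 12. Of the 4 lists of the difference, median centring gave 12, both channels above background 7, and leave-outs 1 to 8.

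PRKDC with DNA-PKcs siRNA lay at -1.79 with median centring (adjusted p = 0.19), at -1.04 as first designed (adjusted p = 0.487) and from -1.14 to -1.06 in leave-outs (adjusted p up to 0.228). PARP1 with PARP1 siRNA lay at -1.29 with median centring (adjusted p = 0.605), at -0.37 as first designed, at -1.19 without a filter (adjusted p = 0.138) and from -1.63 to -0.75 in leave-outs, where it passed only without the first PARP1 siRNA array (adjusted p = 0.0457, and 0.057 to 0.119 in the others). Before any dye correction, median centring put PRKDC at -1.78 over the 4 DNA-PKcs siRNA arrays, and PARP1 at -2.10 on the second PARP1 siRNA array, the only one with a matching file, against -0.72 in the value table. It also put PARP1 at -1.33 and -1.36 on DNA-PKcs siRNA arrays 3 and 4, and PRKDC at -1.245 on the second PARP1 siRNA array. All of these had the siRNA RNA in Cy3, so the -2.10 does not measure the knockdown alone. As first designed, the PARP1 siRNA arrays correlated at -0.888 and the comparisons at -0.0222.

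Signs that turned with DNA-PKcs siRNA were those of PARP1 (-0.0161 without background correction, -0.00573 with an offset of 0, -0.79 with median centring, -0.0159 as first designed and with the 5 matching files, -0.0314 to 0.041 in leave-outs). With median centring KLK3 lay at -0.41, PLA1A at -0.11, LIG4 at 0.0315, FANCC at -0.10, ISG20 at -0.0728 and BAX at -0.16. With the mean of probes KLK3 lay at -0.58, CENPF at 0.19 and LIG3 at 0.53. With PARP1 siRNA as first designed PRKDC lay at 0.41, KLK3 at -0.0683, TMPRSS2 at 0.0394, FOXN2 at -0.19, DDX17 at -0.0355, RASSF4 at -0.0453, IGHA1 at 0.0271, SDR9C7 at 0.0112, CAMKMT at 0.16, CCNE2 at 0.0661, HMGCS1 at 0.0245, FANCE at 0.0344, MAF at 0.00311, EIF2AK2 at -0.0908, PARP14 at -0.12, BAX at -0.00972 and HRK at -0.0272. With the mean of probes PRKDC lay at 0.28 and LIG3 at 0.34. HRK lay at -0.14 without background correction and with the 5 matching files, at -0.17 with an offset of 0 and at -0.18 with median centring. For the difference, the dim ZNF43 and KRT84 both lay at -0.11 with median centring. Except where fewer samples, more genes tested or the mismatched file show it, the cause was not tested.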

Other observations

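Among p53 targets, 6 of 27 rose and 3 fell with DNA-PKcs siRNA (adjusted over the list alone, 6 and 2; median -0.0591; camera adjusted p = 0.952). MDM2, the ubiquitin ligase of p53, rose to 1.34 ± 0.32 on its brighter probe, PHLDA3 to 0.67 ± 0.02 and the apoptosis effector BAX to 0.65 ± 0.06 (-0.16 with median centring), while the nuclease AEN fell to -1.34 ± 0.13. The BAX value is that of its brightest probe, and its other probes, at 0.46 and -0.09, did not pass. With PARP1 siRNA 3 of 27 rose and 2 fell, adjusted over the list alone as well (median -0.0737; camera adjusted p = 0.842), with AEN at -1.18 ± 0.40. Of 34 apoptosis regulators 7 rose and 2 fell with DNA-PKcs siRNA, adjusted over the list alone as well (median 0.0617; camera adjusted p = 0.31), and 4 rose and 0 fell with PARP1 siRNA (the same adjusted over the list alone; median 0.0109; camera adjusted p = 0.367). The caspase inhibitor XIAP rose to 1.30 ± 0.08 and 1.25 ± 0.29, and the BH3-only gene HRK to 0.71 ± 0.02 and 0.93 ± 0.10 on its brighter probe. The HRK value with PARP1 siRNA turned to between -0.18 and -0.0272 in every scanner-based alternative with other background correction or centring, and its other probe read -0.12. In the unfolded protein and ATF4 response 5 of 29 rose and 6 fell with DNA-PKcs siRNA, adjusted over the list alone as well (median 0.0462; camera adjusted p = 0.952), with DNAJC3 at 1.34 ± 0.32 and the mitochondrial folate enzyme MTHFD2 at -1.22 ± 0.12. With PARP1 siRNA 1 rose and 5 fell (adjusted over the list alone, 2 and 5; median -0.00517; camera adjusted p = 0.55). In hypoxia and glycolysis 4 of 31 rose and 5 fell with DNA-PKcs siRNA, adjusted over the list alone as well (median -0.237; camera adjusted p = 0.219). VEGFA, the angiogenic growth factor, rose to 1.06 ± 0.31 on its brightest probe with another at -0.48, and the glycolytic enzyme ENO1 fell to -1.06 ± 0.10. With PARP1 siRNA 2 rose and 1 fell (adjusted over the list alone, 1 and 0; median -0.145; camera adjusted p = 0.296), ENO1 at -0.94 ± 0.35.

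The remaining lists did not pass. With DNA-PKcs siRNA they were neuroendocrine markers (3 of 11 higher, 1 lower; adjusted over the list alone, 3 and 2; camera adjusted p = 0.169), histone genes (2 of 19 higher, 1 lower; the same alone; 0.372), ribosomal proteins (9 of 56 higher, 7 lower; 8 and 4 alone; 0.605), Wnt and stem-cell genes (4 of 27 higher, 5 lower; 4 and 4 alone; 0.786), and epithelial adhesion genes (4 of 29 higher, 1 lower; 0 and 0 alone; 0.786). ADP-ribosylation enzymes (4 of 28 higher, 5 lower; the same alone; 0.865), mesenchymal and invasion genes (2 of 26 higher, 5 lower; 2 and 3 alone; 0.879), leukocyte markers (1 of 6 higher, 1 lower; the same alone; 0.952) and endothelial markers (0 of 5 higher, 1 lower; the same alone; 0.978) followed. With PARP1 siRNA the camera adjusted p was 0.0532 for DNA damage signalling (1 higher, 2 lower; 1 and 3 alone), 0.0583 for heat shock and chaperones (1 and 2; 1 and 6 alone), 0.102 for non-homologous end joining (0 and 1; the same alone), 0.168 for NF-kB and inflammatory genes (0 and 0; 5 and 0 alone), 0.267 for fibroblast markers (0 and 0; the same alone) and 0.297 for oxidative phosphorylation (2 and 6; 3 and 7 alone). It was 0.337 for histone genes (1 higher, 0 lower; the same alone), 0.362 for endothelial markers (0 and 1, ENG; the same alone), 0.364 for mesenchymal and invasion genes (0 and 2; the same alone), 0.55 for neuroendocrine markers (0 and 0; the same alone) and 0.555 for leukocyte markers (0 and 1, CD14; 1 and 1 alone). It was 0.752 for epithelial adhesion genes (0 and 0, the same alone), 0.842 for Wnt and stem-cell genes (2 and 0, with 1 and 0 alone), and 0.979 for ADP-ribosylation enzymes (1 and 1, with 0 and 0 alone) and ribosomal proteins (2 and 3, with 0 and 0 alone). Some medians differed between the first and the second PARP1 siRNA array: DNA damage signalling lay at -0.193 and -0.546, and heat shock and chaperones at -0.205 and -0.536. Oxidative phosphorylation lay at -0.0167 and -0.252, hypoxia and glycolysis at -0.000991 and -0.262, and neuroendocrine markers at 0.00256 and 0.664. Non-homologous end joining lay at -0.17 and -0.182.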
